A study of Sus scrofa with 36 samples.

How the data were processed

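The data are RNA levels in the hippocampus of 36 male piglets on Affymetrix porcine genome arrays, 1 array per sample, in 3 feeding groups of 12. The authors deposited log2 values for each probe set, made with RMA in Affymetrix Expression Console 1.1 per the submitters' processing notes. RMA corrects background, normalises arrays to a common distribution and summarises the probes of a set. Each deposited value is rounded to 1 decimal. The table lists 23999 probe sets besides 124 array controls. No raw intensities were used, and the number of arrays limits the precision.

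Gene names came from the array annotation of 2016. It gave exactly 1 gene symbol to 10069 of 23999 probe sets without controls, several to 198 and none to 13732. By gene ID, 9989 of these names were matched to the RefSeq table, and 10 older symbols were used to match list genes. Probe sets with no name or several were tested but not named. Array controls were left out, and so were probe sets with a mean below the 25th percentile (log2 4.92), which left 18006.

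Groups were compared in R 4.3.3 with limma 3.58.1. A linear model held the group and the set code as a fixed block over the 36 samples. Moderated statistics (eBayes), two-sided, were adjusted by Benjamini-Hochberg over 18006 probe sets, with a threshold of 0.05. The contrasts were medium dose minus control, high dose minus control and high minus medium dose, with an F test of any difference and an ordered trend. Gene lists, 33 in number with 1096 symbols, were tested with camera at a preset inter-gene correlation of 0.01, on 1 probe set per gene (the highest mean), and adjusted over 33 lists per contrast. A list mean was also tested by permuting labels within set codes 100000 times. Relations across arrays were tested with 100000 resamples, all two-sided. Arrays were counted as having the polyadenylated spike-in control Dap above a log2 value of 6. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

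The lists, the contrasts, the other settings listed next and the rule for named genes were fixed before the data were examined. The rule takes the 12 largest changes in each direction that passed, or, where fewer than 10 passed, the 10 genes with the smallest unadjusted p, said not to pass. It adds up to 3 members with the smallest p of each list discussed, and BDNF, NTRK2, CREB1, NCAM1, ST8SIA2, ST8SIA4, GNE, LTF, TFRC, FOS, ARC, TTR, MBP and GFAP wherever measured.

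The other settings fixed in this way were no set block, a replicate block in place of the set block or with it, a random set block, other filters on dim probe sets (none, or the 50th percentile), centring or quantile normalisation on top, array weights, ordinary tests, a robust trended eBayes, and 1 probe set per gene. Fits of 2 groups alone, fits without each set code, the means of the choroid plexus and oligodendrocyte lists as covariates, an estimated inter-gene correlation, fry, and the mean of all probe sets of a gene were fixed too. Added after the data had been seen were a labelling block, leaving out the 3 arrays of lowest correlation, leaving out each sample, random amounts within the rounding, and the permutation of list means. The samples were regrouped within set codes to give 100 splits, the real one included, as fixed in advance for counts at unadjusted p under 0.05 and extended later to the other counts and to list means. After the data had been seen, list means were also fitted within the arrays that had the spike-in control, and the overlap of both doses was counted in those splits and in 100 simulated sets of unchanged groups with shared controls.

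The model was tested on simulated data, with independent noise for each probe set and 200 of 18006 changed in each of 5 runs. For medium dose minus control it recovered 65.3% of 1.25-fold, 94.4% of 1.5-fold and 97.7% of 2-fold changes. For high dose minus control these were 64.3%, 93.2% and 97.4%, and for high minus medium dose 64.3%, 94.4% and 97%. The real arrays share variation that such noise lacks, so recovery in them may differ.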

Results

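Hippocampal transcripts were measured on porcine expression arrays in 36 male Landrace by Large White piglets, 12 per group. From day 3 to day 38 the piglets received a milk replacer with its basal content of lactoferrin (control) or one with added lactoferrin, an iron-binding milk glycoprotein, at 0.6 g/L (medium dose) or 1.2 g/L (high dose). The basal level was not quantified in the labels. Each sample also carried 1 of 5 set codes, S1 to S5, whose meaning the labels do not give; S1 held no medium-dose sample. The deposited log2 values covered 23999 probe sets besides 124 array controls, and 18006 were tested. Of these, 8372 named exactly 1 gene, and together they named 6034 genes. Array medians lay between 6.6 and 6.7, the mean correlation of an array with the others was 0.983, and no arrays were duplicates of each other. High-dose replicate 2 stood apart, with a mean correlation of 0.961, the highest oligodendrocyte mean (10.78) and the lowest neuron mean (10.09). The number of arrays limits the precision. P-values of single probe sets and of permuted list means measure the spread between samples. Camera with a preset correlation instead compares a list's genes with all other genes, so its small p-values do not measure that spread.

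Along the main axis of variation between arrays, oligodendrocyte and neuron transcripts ran in opposite directions. The first principal component held 19.4% of the variance. It rose with the mean of 19 oligodendrocyte and myelin genes (Pearson r = 0.856, permutation p = 1e-05, Spearman rho = 0.797, permutation p = 1e-05, r = 0.709 without the 2 arrays farthest from the median). It fell with the mean of 15 neuron genes (r = -0.867, permutation p = 1e-05, rho = -0.708, permutation p = 1e-05, r = -0.697 without 2 arrays). A p of 1e-05 is the smallest that the resampling can give. The component was computed from the same probe sets, and only these 2 of the 33 list means were tested against it. Other lists may therefore follow it too. The oligodendrocyte mean and the neuron mean were related by r = -0.797 (permutation p = 1e-05) and rho = -0.639 (permutation p = 5e-05), or r = -0.588 without 2 arrays. Over the 10 relations of this family, the adjusted p of r was 3.3e-05 for each of these 3. By spike-in control that relation was r = -0.703 (permutation p = 0.00017) in the 26 arrays with a polyadenylated spike-in control (Dap) present and r = -0.9 (permutation p = 0.0017) in the 10 arrays without it. Within set codes it was r = -0.781 in S2 (permutation p = 0.0053, r = -0.368 without 2 arrays). In S3 it was r = -0.477 (permutation p = 0.23, r = -0.214 without 2 arrays). In S4 it was r = -0.523 (permutation p = 0.15, r = 0.135 without 2 arrays), so in S3 and S4 it did not pass. The component was also related to signs of RNA quality and hybridisation. Against the difference between 3′ and 5′ actin probe sets r was -0.561 (permutation p = 0.00047, adjusted p = 0.00094) and rho -0.354 (permutation p = 0.034), or r = -0.281 without 2 arrays. Against the hybridisation control bioB r was 0.479 (permutation p = 0.0058, adjusted p = 0.0072) and rho 0.314 (permutation p = 0.063), or r = 0.152 without 2 arrays, so both relations rest largely on those arrays. The component was not detectably related to the feeding groups (permutation p = 0.202) and missed the threshold for the spike-in control (permutation p = 0.0131, adjusted p = 0.0524 over 12 tests). The spike-in control was absent in 3 control, 3 medium-dose and 4 high-dose arrays, and the labels do not say whether these were labelled separately. In set codes shared by the compared groups, only 1 to 3 arrays per group lacked it, too few for shifts of their own. Gene list shifts by spike-in control are therefore given for the arrays that had it, with the set code as a block. Among those arrays control replicate 9 was the only S4 control, so their shifts against control in S4 rest on it.

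**Figure D1:**
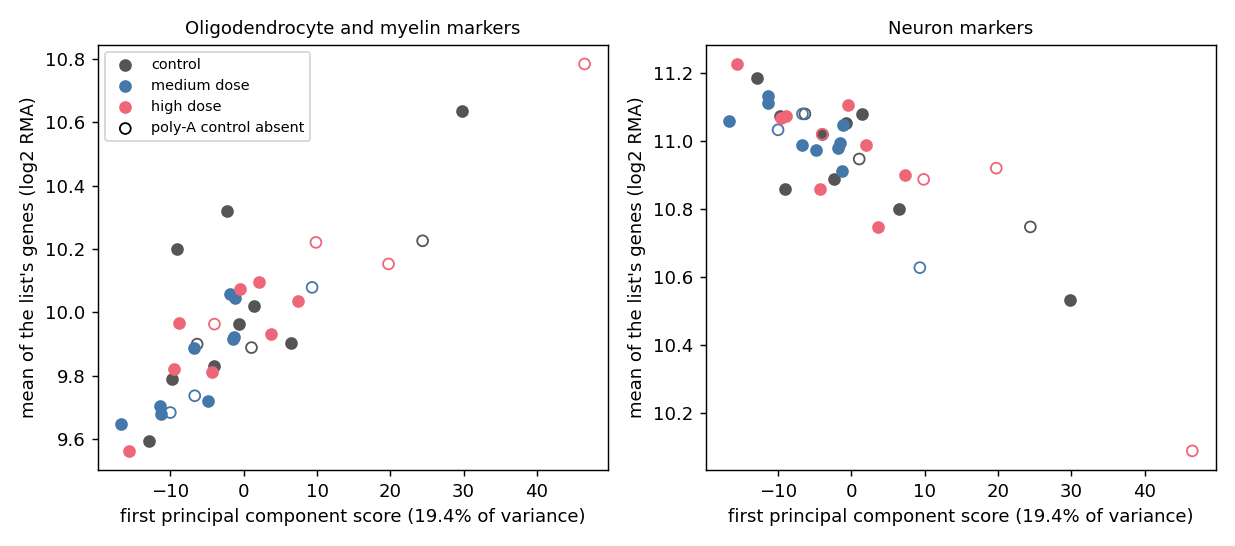
Mean log2 level of oligodendrocyte and myelin genes (left) and of neuron genes (right) against the score on the first principal component, 1 point per array, coloured by group; open points are arrays without the polyadenylated spike-in control. Oligodendrocyte means rise (r = 0.856) and neuron means fall (r = -0.867) along the component, and arrays of the 3 groups are mixed along it.

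The comparison of medium dose with control asks which hippocampal transcripts differed at the lower supplement. Genes of interferon response and antigen presentation lay lower in the medium-dose samples by a test with a preset correlation, but not with an estimated correlation (adjusted p = 0.412). Their mean level was 7.32 ± 0.37 (SD, n = 12) against 7.76 ± 0.62 (SD, n = 12) in controls, a mean log2 difference of -0.44 over 30 genes, each of which lay below 0 and none of which passed over all probe sets. BDNF, the neurotrophin of hippocampal plasticity, was measured at 9.20 ± 0.36 against 8.82 ± 0.23 (SD, n = 12 each), a log2 difference of 0.36 with a 95% interval from 0.08 to 0.63. It lay above the control median in 10 of 12 medium-dose samples, with unadjusted p = 0.0126 and adjusted p = 0.617 in limma, so it did not pass. No probe set passed an adjusted p of 0.05 in limma, where the smallest adjusted p was 0.153. At unadjusted p under 0.05 there were 1248 of 18006, against 900 by chance, with 680 higher and 568 lower.

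The interferon list was called by camera with a preset inter-gene correlation of 0.01 (adjusted p = 2.96e-17 over 33 lists). With an estimated correlation its p was 0.0212, fry gave p = 0.016 and adjusted p = 0.306, and a permutation of the list mean gave p = 0.0202 and adjusted p = 0.415. Of its 30 genes, 16 were lower at unadjusted p under 0.05, 9 were lower when adjusted over the list alone, and 0 when adjusted over all probe sets. The smallest p-values belonged to SLA-2 (-0.48, SE 0.14, p = 0.0025) and B2M (-0.48, SE 0.15, p = 0.00313), parts of the class I antigen-presenting complex, and to the interferon-induced GTPase GBP1 (-1.34, SE 0.42, p = 0.00328). Transcripts of the SLA family are similar enough to cross-hybridise. The shift was not the same in each set code. It was -0.23 in S2, -0.31 in S3, -1.10 in S4 and 0.02 in S5, and without the S4 samples it was -0.20. It was -0.39 (SE 0.23) in the arrays with the spike-in control.

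**Figure D2:**
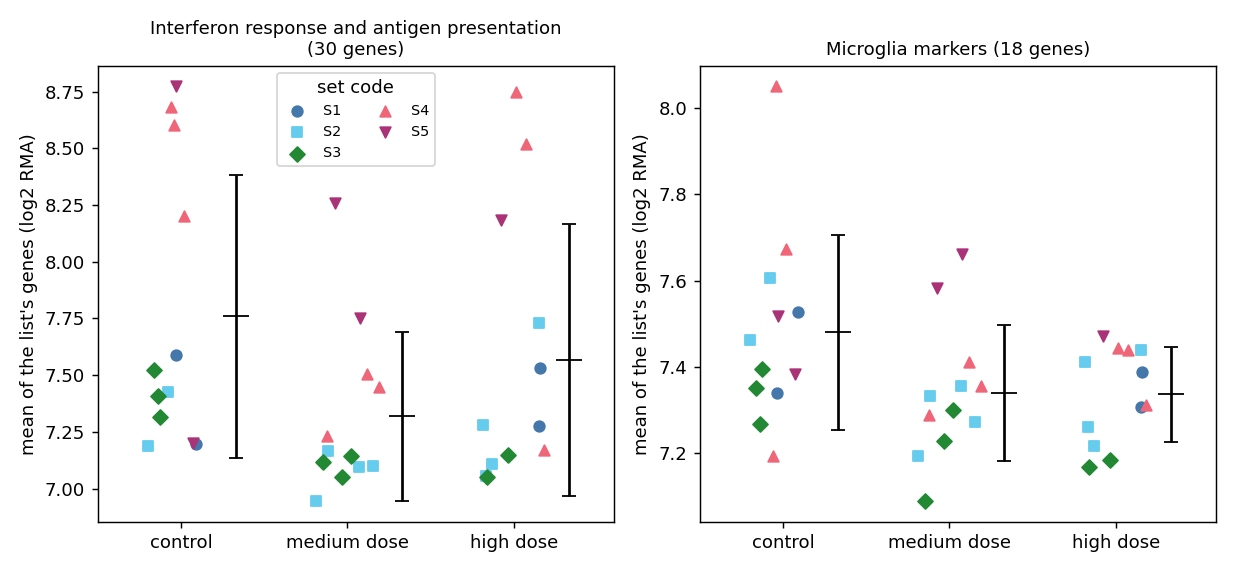
Mean log2 level of 30 interferon response and antigen presentation genes (left) and 18 microglia markers (right) in each sample, by group and set code; horizontal ticks and bars give the mean and SD of 12 samples. Interferon means spread widely within groups, with the samples above 8 coming from S4 and S5. The microglia means have an SD of 0.23 in controls, which is 0.14 without control replicate 9, against 0.16 at the medium and 0.11 at the high dose.

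Glial and immune lists also lay lower at the medium dose. Microglia markers averaged 7.34 ± 0.16 against 7.48 ± 0.23 (SD, n = 12 each), with a mean log2 difference of -0.14 over 18 genes and 6 lower at unadjusted p under 0.05 (camera adjusted p = 0.000141, p = 0.0662 with an estimated correlation). Without control replicate 9 this difference was -0.09, still called. Their smallest p-values belonged to the lysosomal protease CTSS (-0.46, SE 0.17, p = 0.0105), the myeloid transcription factor IRF8 (-0.19, SE 0.08, p = 0.017) and the microglial ADP receptor P2RY12 (-0.27, SE 0.11, p = 0.0172). Oligodendrocyte and myelin markers differed by -0.15 over 19 genes (camera adjusted p = 0.00757, p = 0.253 with an estimated correlation), with CNP at -0.58 (SE 0.21, p = 0.00784), CLDN11 at -0.16 (SE 0.10, p = 0.0946) and PLLP at -0.26 (SE 0.15, p = 0.0963). The shift of this list was -0.07 when control replicate 4 was left out, and the call ended. That array had a mean correlation of 0.976 with the others. Of the controls it had the highest oligodendrocyte mean (10.64) and the lowest neuron mean (10.53). Innate immunity genes differed by -0.09 over 20 genes (camera adjusted p = 0.0473, p = 0.179 with an estimated correlation), among them the complement genes C4A (-0.51, SE 0.21, p = 0.0226) and C3 (-0.24, SE 0.13, p = 0.0854) and the receptor TLR2 (-0.22, SE 0.12, p = 0.0914). Without control replicate 9 this shift was -0.05 and the call ended. Cytosolic ribosomal protein genes differed by -0.07 over 55 genes, 51 of them below 0 (camera adjusted p = 7.43e-09, p = 0.204 with an estimated correlation). RPL7 (-0.12, SE 0.05, p = 0.0261), RPL38 (-0.11, SE 0.05, p = 0.0395) and RPS15 (-0.15, SE 0.07, p = 0.0421) had the smallest p-values, in a family whose members can cross-hybridise. Within the 4 set codes with both groups, the oligodendrocyte list lay lower in 4 and the microglia, innate immunity and ribosomal lists in 3 each. Sizes were uneven. Innate immunity shifted by -0.337 in S4 but by -0.010 in S2, -0.098 in S3 and 0.048 in S5, and its call ended without S3 or S4. The ribosomal list shifted by -0.185 in S2 but by -0.018 in S3, 0.002 in S4 and -0.074 in S5. With the spike-in control present, the shift was -0.12 (SE 0.14) for oligodendrocytes, -0.18 (SE 0.10) for microglia, -0.15 (SE 0.09) for innate immunity and -0.07 (SE 0.05) for ribosomal genes.

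Neurotrophin and growth factor genes lay higher at the medium dose, by 0.07 over 17 genes (camera adjusted p = 0.0428, p = 0.025 and adjusted p = 0.412 with an estimated correlation). FGFR1 (0.21, SE 0.08, p = 0.0107), the binding protein IGFBP2 (0.20, SE 0.08, p = 0.0134) and EGFR (0.14, SE 0.06, p = 0.0279) had the smallest p-values. The list lay higher in 3 of 4 set codes, and by 0.06 (SE 0.05) with the spike-in control present. This call held in 26 of the 36 fits that left out 1 sample and in 9 of 22 other settings. BDNF and TrkB signalling genes, of which 21 of 55 could be measured, differed by 0.03 and were not called (camera p = 0.161). Besides BDNF, the transcription factor STAT3 was at -0.12 (SE 0.05, p = 0.0382) and the calcium channel ITPR1 at 0.14 (SE 0.07, p = 0.0526). Among 14 sialylation genes, which were not called (camera p = 0.176), the polysialyltransferase ST8SIA4 was at -0.21 (SE 0.10, p = 0.0487), with ST3GAL3 at -0.28 (SE 0.12, p = 0.0227) and the sialic acid lyase NPL at -0.20 (SE 0.10, p = 0.046). In the circadian clock list (9 genes, camera adjusted p = 0.127), the deubiquitinase USP2 passed when adjusted over the list alone (0.22, p = 0.00396, adjusted p = 0.0357). The remaining lists had camera adjusted p-values of 0.117 or more.

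The 10 genes with the smallest unadjusted p between medium dose and control did not pass, with adjusted p from 0.407 to 0.515. Higher in the medium-dose group were CD93, a glycoprotein of endothelial and myeloid cells (0.40, SE 0.09, p = 0.000165, 11 of 12 samples above the control median), FKBP1A, the binding protein of FK506 (0.26, SE 0.06), and the podosome scaffold SH3PXD2A (0.28, SE 0.07). So were glycogen synthase GYS1 (0.17, SE 0.04), the adenosine receptor ADORA1 (0.25, SE 0.07, adjusted p = 0.00828 over the receptor list alone), NREP (0.31, SE 0.08) and the actin crosslinker ACTN2 (0.43, SE 0.12). Lower were the complement regulator CD55 (-0.57, SE 0.14), NOSTRIN, which binds endothelial nitric oxide synthase (-0.47, SE 0.11), and the inflammatory protease CASP1 (-0.47, SE 0.13). With the medium-dose and control samples fitted alone, 11 probe sets passed, 10 higher and 1 lower. They included FADS6 (0.36, SE 0.05, adjusted p = 0.0094, against 0.64 with all samples), SH3PXD2A (0.31, SE 0.06) and FKBP1A (0.30, SE 0.06), the genes with a name among the 11, of which FADS6 was chosen after its values were seen.

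The comparison of high dose with control asks the same at the larger supplement. Microglia markers lay lower in the high-dose samples by a test with a preset correlation, but not with an estimated correlation (adjusted p = 0.493). Their mean was 7.34 ± 0.11 against 7.48 ± 0.23 (SD, n = 12 each), a mean log2 difference of -0.14 in which each of the 18 genes lay below 0. P2RY12 was measured at 9.58 ± 0.19 against 9.91 ± 0.35, a log2 difference of -0.35 (SE 0.10, p = 0.00217), and 12 of 12 high-dose samples lay below the control median. The complement component C1QA (-0.23, SE 0.09, p = 0.0205) and the microglial marker AIF1 (-0.20, SE 0.09, p = 0.0455) followed. BDNF was at 8.93 ± 0.37, a log2 difference of 0.12 from control (SE 0.13, p = 0.364). No probe set passed in limma, where the smallest adjusted p was 0.906, and 889 were at unadjusted p under 0.05, with 499 higher and 390 lower, against 900 by chance.

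Camera called the microglia list with an adjusted p of 7.74e-07. With an estimated correlation its p was 0.0208, fry gave p = 0.0283, and the permutation of the list mean gave p = 0.0267 and adjusted p = 0.828. At unadjusted p under 0.05 there were 4 lower genes, of which 1 (P2RY12) was lower when adjusted over the list alone. The shift was -0.09 in S1, -0.20 in S2, -0.16 in S3, -0.24 in S4 and 0.02 in S5. It was -0.09 without control replicate 9, the control with the highest microglia mean, and -0.14 (SE 0.06) with the spike-in control as a second block. In the arrays with the spike-in control it was -0.29 (SE 0.08), but control replicate 9 was the only S4 control among them.

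At the high dose, receptors for monoamines, acetylcholine and peptides lay higher by 0.07 over 16 genes, 14 of them above 0 (camera adjusted p = 0.0238, p = 0.0299 and adjusted p = 0.493 with an estimated correlation). The somatostatin receptors SSTR1 (0.15, SE 0.06, p = 0.0153) and SSTR3 (0.10, SE 0.05, p = 0.0677) and ADORA1 (0.10, SE 0.06, p = 0.119) had the smallest p-values. Ribosomal protein genes differed by -0.04 (camera adjusted p = 0.00121, p = 0.416 with an estimated correlation), with RPL7 at -0.14 (SE 0.05, p = 0.00681), RPL37 at -0.13 (SE 0.08, p = 0.11) and RPS28 at -0.07 (SE 0.04, p = 0.111). Within the 5 set codes, the receptor list lay higher in 4 and the ribosomal list lower in 4. With the spike-in control present, the shift was 0.12 (SE 0.04) for receptors and -0.08 (SE 0.07) for ribosomal genes. The ribosomal call ended without control replicate 4, with a shift of -0.014, as it did without high-dose replicate 1 (-0.016), 3 (-0.022) or 7 (-0.022), and without control replicate 8 the shift was -0.059. Interferon genes differed by -0.13 (camera adjusted p = 0.0238, p = 0.42 with an estimated correlation). Their members with the smallest p were the antigen peptide transporter TAP1 (-0.28, SE 0.15, p = 0.0729), with another probe set opposite at unadjusted p under 0.05, the kinase EIF2AK2 (-0.27, SE 0.17, p = 0.117) and OAS1 (-0.47, SE 0.32, p = 0.153). Within set codes the interferon shift had both signs, from -0.35 in S4 to 0.20 in S5, and it was -0.25 (SE 0.22) with the spike-in control present. The call ended without high-dose replicate 9 (-0.03), control replicate 8 (-0.08) or control replicate 11 (-0.08), while the shift was -0.20 without high-dose replicate 10 and -0.22 without control replicate 12. The remaining lists had camera adjusted p-values of 0.251 or more. In the iron list, HAMP, the gene of the iron hormone hepcidin, was at 0.20 (SE 0.08, p = 0.0232), and the haem oxygenase HMOX2 at 0.13 (SE 0.06, p = 0.0279).

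The 10 genes with the smallest unadjusted p between high dose and control did not pass, each with adjusted p = 0.976. Higher were the transcription factor WT1 (0.28, SE 0.07, p = 0.000589), the actin bundler FSCN1 (0.23, SE 0.06), PHEROC (0.27, SE 0.07) and the vascular growth factor receptor FLT1 (0.26, SE 0.08). Lower were D-aspartate oxidase DDO (-0.29, SE 0.08, p = 0.000617), FUBP3 (-0.38, SE 0.11), P2RY12, WDR93 (-0.27, SE 0.08), the small GTPase RALB (-0.21, SE 0.07) and the ion channel kinase TRPM7 (-0.24, SE 0.08).

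Genes fixed in advance for this diet showed no difference past the threshold at either dose. The transferrin receptor TFRC was at 0.00 at both doses (SE 0.07 each), the adhesion molecule NCAM1 at 0.01 and -0.09 (SE 0.08 and 0.07), the myelin gene MBP at -0.04 and 0.04 (SE 0.06 and 0.05) and the astrocyte gene GFAP at -0.06 and 0.05 (SE 0.10 each), medium dose first. The sialic acid synthesis gene GNE was at 0.09 and -0.01 (SE 0.07 each), CREB1 at -0.03 and -0.10 (SE 0.06 each), FOS at -0.07 and 0.04 (SE 0.17 each), and ST8SIA4 at -0.21 and -0.16 (SE 0.10 each). TTR, a choroid plexus transcript, varied so widely that its differences of 0.18 and 0.01 carried an SE of 0.32 and 0.31. The lactoferrin gene itself, LTF, lay below the level of testing, at 4.60 ± 0.30, 4.53 ± 0.21 and 4.59 ± 0.18 in control, medium and high dose (SD, n = 12 each). No probe set carried the name of NTRK2, ST8SIA2 or ARC.

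**Figure D3:**
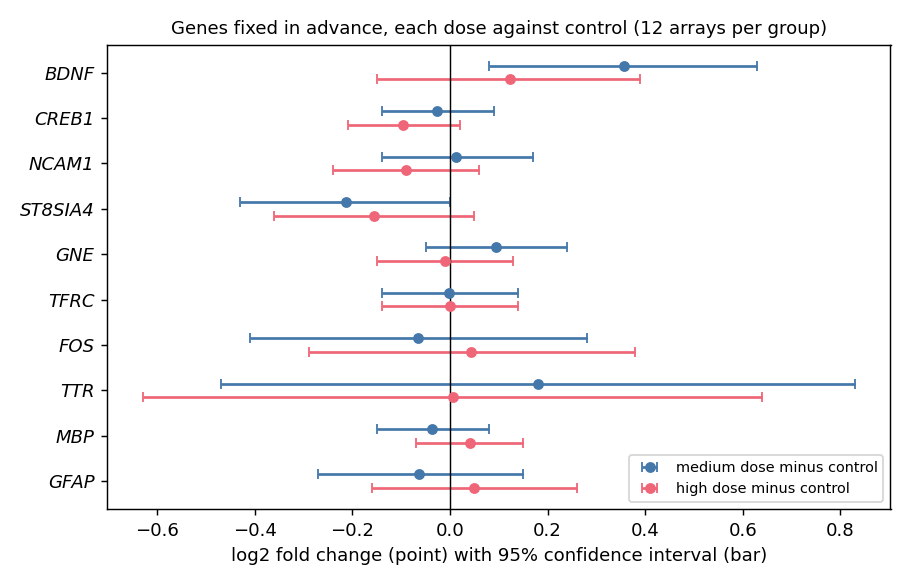
Log2 fold change of each dose against control for the fixed genes with a tested probe set, with 95% confidence intervals (bars) from 12 samples per group. The BDNF interval at the medium dose runs from 0.08 to 0.63, while at the high dose the difference is 0.12.

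The comparison of high with medium dose asks whether doubling the supplement made a difference. Interferon genes lay higher at the high dose by a test with a preset correlation, but not with an estimated correlation (adjusted p = 0.666). Their mean was 7.57 ± 0.60 against 7.32 ± 0.37 (SD, n = 12 each), a mean log2 difference of 0.31 over 30 genes, with 28 above 0. Oligodendrocyte and myelin markers lay higher by 0.15 over 19 genes, at 10.04 ± 0.29 against 9.84 ± 0.16, again not with an estimated correlation (p = 0.181). Neuron markers differed by -0.05, with 12 of 15 genes below 0 (not called, camera adjusted p = 0.398), and the difference between 3′ and 5′ actin probe sets was 0.30 ± 0.20 at the high dose against 0.48 ± 0.19 at the medium dose (SD, n = 12 each). BDNF differed by -0.23 (SE 0.14, p = 0.0928). No probe set passed in limma, where the smallest adjusted p was 0.285, and 1076 were at unadjusted p under 0.05, with 447 higher and 629 lower.

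Between the doses, the interferon list was called by camera (adjusted p = 6.67e-10, p = 0.0753 with an estimated correlation), with SLA-2 at 0.39 (SE 0.14, p = 0.0105), ISG15 at 0.77 (SE 0.32, p = 0.0209) and SLA-3 at 0.44 (SE 0.19, p = 0.0251). Its shift was 0.22 in S2, -0.01 in S3, 0.75 in S4 and 0.18 in S5, and 0.36 (SE 0.23) with the spike-in control present. The oligodendrocyte list had a camera adjusted p of 0.00159 (p = 0.181 with an estimated correlation), with CRYAB at 0.36 (SE 0.17, p = 0.0373), CNP at 0.44 (SE 0.21, p = 0.0392) and MAG at 0.27 (SE 0.15, p = 0.0764). Leaving out high-dose replicate 12 ended this call, with a shift of 0.11. The 3 measured oligodendrocyte precursor markers differed by 0.16 (camera adjusted p = 0.0439, p = 0.0935 with an estimated correlation), OLIG1 at 0.18 (SE 0.09, p = 0.0463), OLIG2 at 0.15 (SE 0.09, p = 0.0997) and VCAN at 0.14 (SE 0.11, p = 0.203). Innate immunity genes differed by 0.09 (camera adjusted p = 0.0263, p = 0.122 with an estimated correlation), with C4A at 0.46 (SE 0.21, p = 0.0373), IL1R1 at 0.18 (SE 0.10, p = 0.066) and SOCS3 at 0.12 (SE 0.07, p = 0.101). Ribosomal protein genes differed by 0.03 (camera adjusted p = 0.0295, p = 0.549 with an estimated correlation), with RPS15 at 0.14 (SE 0.07, p = 0.0537), RPL23 at 0.10 (SE 0.06, p = 0.141) and RPL37 on the other side at -0.14 (SE 0.08, p = 0.0818). This small shift turned to -0.04 with replicate number and set code both as blocks. It was 0.017 and no longer called without high-dose replicate 8, and 0.049 without high-dose replicate 3 or medium-dose replicate 6. Within the 4 set codes with both doses, both oligodendrocyte lists lay higher in 4, and the innate immunity and ribosomal lists in 3 each. Sizes were uneven here too. The oligodendrocyte shift was 0.345 in S3 and 0.437 in S5, which held 1 high-dose array, but 0.075 in S2 and 0.042 in S4. For the precursors these shifts were 0.428 and 0.35 against 0.058 and 0.056. The ribosomal shift was 0.077 in S2 but -0.002 in S3, 0.004 in S4 and 0.025 in S5, and its call ended without S2 or S5. With the spike-in control present, the shift was 0.10 (SE 0.08) for oligodendrocytes, 0.11 (SE 0.09) for their precursors, 0.07 (SE 0.05) for innate immunity and 0.03 (SE 0.04) for ribosomal genes. The remaining lists had camera adjusted p-values of 0.118 or more. In the list of lactoferrin and its possible receptors, which was not called, LRP8 was at -0.17 (SE 0.06, p = 0.00892). Whether LRP8 acts as a receptor for lactoferrin was not tested.

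The 10 genes with the smallest unadjusted p between the doses did not pass, with adjusted p from 0.748 to 0.811. Lower at the high dose were C9H1orf21 (-0.26, SE 0.07, p = 0.000388), the elastin crosslinking enzyme LOXL1 (-0.45, SE 0.12), GSE1 (-0.27, SE 0.07), the transcriptional coactivator PPRC1 (-0.17, SE 0.05), the Rac activator TIAM2 (-0.59, SE 0.17), the dermatan sulfate epimerase DSE (-0.34, SE 0.10) and the ubiquitin ligase RNF185 (-0.22, SE 0.07). Higher were the zinc finger gene ZNF655 (0.24, SE 0.06), CLIC2 (0.45, SE 0.12) and the actin-binding TAGLN2 (0.26, SE 0.08). Across the 3 groups together, no probe set passed for any difference (smallest adjusted p = 0.386 in limma, 1061 at unadjusted p under 0.05) or for an ordered dose trend (0.8 and 885).

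None of the list calls in the 3 comparisons held after adjustment with an estimated correlation or with fry, whose PValue tests whether a list's genes move on balance one way. The fold changes of both doses against control were correlated across genes (r = 0.451 over 18006 probe sets, which are not independent replicates). Unchanged groups simulated against shared controls gave r = 0.494 ± 0.01 (SD). That simulation draws the noise of each probe set independently, so its spread is too narrow to judge r by. The 99 other splits of the real samples gave r = 0.517 ± 0.154 (SD), from 0.076 to 0.834. The covariance was 0.00395 in the data and 0.00395 in the simulation, a difference of -1.12e-06. In the 99 other splits it was 0.00432 ± 0.00215 (SD), with up to 0.0112. The match with the simulation is therefore much closer than the spread of real samples can resolve. With the controls split into 6 and 6, the mean r was -0.015 in the data and -0.037 in the simulation. At unadjusted p under 0.05, 112 probe sets were higher at both doses and 89 lower, where independent lists would share 18.8 and 12.3. Unchanged groups simulated with shared controls shared 87.2 ± 9.2 and 89.6 ± 10.3 (SD), and 99 other splits of the real samples shared a median of 63 and 59, with up to 605 and 725.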

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

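The labelling block, the sets without the 3 arrays of lowest correlation or without each sample, the random amounts within the rounding and the permutation of list means were chosen after the data had been seen. In limma, 0 probe sets passed between high dose and control in the 22 settings other than single samples left out, and 0 for any difference and for the trend in the 21 that give them. Between medium dose and control 11 passed with those 2 groups alone and 4 without S1, and between the doses 1 with array weights. Leaving out each sample gave 0 to 1 between medium dose and control (1 without medium-dose replicate 12), 0 to 1 between the doses and 0 to 1 for any difference (1 each without medium-dose replicate 11), and 0 to 0 for high dose against control and for the trend.

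Probe sets at unadjusted p under 0.05 between medium dose and control numbered 424 with 1 probe set per gene, where fewer are tested, and 1902 with 2 groups alone. Between high dose and control they numbered 276 with 1 probe set per gene, 469 with the filter at the 50th percentile and 1351 with no filter. Between the doses they numbered 292, 715 with the filter at the 50th percentile, 1672 with array weights, 2560 without S2, 554 without S3, and 1785 with replicate block and set block together. Leaving out each sample gave 931 (control replicate 4) to 1877 (high-dose replicate 2), 599 (control replicate 3) to 1312 (high-dose replicate 1), and 708 (high-dose replicate 7) to 1915 (medium-dose replicate 1) for the 3 contrasts.

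For medium dose against control, high dose against control and between the doses, lists called numbered 0, 0 and 0 with an estimated correlation and with fry, and 0, 0 and 1 by the permutation of list means. Without the 3 arrays of lowest correlation they numbered 3, 2 and 2. For medium dose against control there were 10 with no set block and 10 with a random set block. For high dose against control there were 2 each with the filter at the 50th percentile, with array weights and without S4. Between the doses there were 2 with no filter, with the covariates and with the mean of all probe sets, and 3 with quantile normalisation and without S4. Leaving out each sample gave 3 to 8, 1 to 5 and 1 to 6, lowest without high-dose replicate 1 for both doses against control and without high-dose replicate 12 between the doses. The correlation of both doses' fold changes was 0.16 with replicate block and set block, 0.61 without S1, 0.034 without S2 and 0.61 with the covariates, and 0.346 (without medium-dose replicate 1) to 0.606 (without high-dose replicate 2) over single samples.

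Ribosomal protein genes between the doses turned from 0.03 to -0.04 with replicate block and set block and to -0.001 with the covariates. Over 15 called lists and 58 alternatives, 680 of 870 values were called again in the same direction, 188 were not called, 0 were called the other way and 2 turned. The call held in 9 of 22 other settings and 26 of 36 fits without 1 sample for neurotrophins, in 17 (of 21, since their own mean as covariate fixes the shift at 0) and 34 for oligodendrocytes (lost without high-dose replicate 1 and control replicate 4) and in 11 and 22 for innate immunity at the medium dose. At the high dose it held in 14 and 23 for interferon, 17 and 31 for ribosomal genes and 12 and 27 for receptors. Between the doses it held in 19 (of 21) and 35 for oligodendrocytes, 8 and 20 for their precursors, 12 and 30 for innate immunity and 12 and 21 for ribosomal genes. The interferon and ribosomal calls at the medium dose, the microglia calls at both doses and the interferon call between the doses were lost only with an estimated correlation, with fry or in the permutation of list means. Of 19746 values of named genes, 4 passed (FKBP1A, SH3PXD2A and ACTN2 at the medium dose), 19503 kept their sign, and 24 took the other sign beyond 1 SE. Replicate numbers gave no sign of pairing, since the mean correlation of same-number deviations was -0.005. With the replicate block in place of the set block, 1361, 694 and 1017 probe sets were at unadjusted p under 0.05, 0 passed, 8, 4 and 6 lists were called and the correlation was 0.459. Except where fewer genes or samples were tested, the cause was not tested. Signal near the background, as for LTF, limits what the arrays show.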

Other observations

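The tests of explanations in this part, the genes named by set code or by spread, and the regrouping of passing probe sets, called lists and list means were chosen after the results were seen, while the regrouping within set codes for counts at unadjusted p was fixed before the data were examined. Set codes differed more than feeding groups did, with 472 of 18006 probe sets past the threshold in limma and 3140 at unadjusted p under 0.05, while presence of the polyadenylated spike-in gave 0 and 2855. Interferon response and antigen presentation was the list of 33 that differed among set codes (permutation p = 0.00029, adjusted p = 0.00957). Its mean was 8.01 ± 0.66 (SD, n = 9) in S4 and 8.03 ± 0.59 (SD, n = 5) in S5, against 7.40 ± 0.19 (n = 4) in S1, 7.21 ± 0.22 (n = 10) in S2 and 7.22 ± 0.18 (n = 8) in S3. B2M, the class I light chain, averaged 12.81 in S4 and 12.84 in S5 but 11.91 in S3 (adjusted p = 0.0111 in limma). ISG15 averaged 9.36 and 9.58 against 7.60 in S3 (adjusted p = 0.0118), and IFIT1 7.93 and 8.10 against 6.47 (adjusted p = 0.0121). Genes outside interferon response also differed, such as GMPR2, from 9.07 in S1 to 9.66 in S4 (adjusted p = 0.00986 in limma).

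The named genes with the widest spread between piglets were of several kinds. The interferon-induced RSAD2 had an SD of 1.53 (4.3 to 9.6) and GBP1 of 1.43 (5 to 9.9), followed by PLAC8 (1.19), SAL1 (1.18), the water channel AQP3 (1.17, 6.2 to 11.4) and ISG15 (1.15, 7.4 to 11.3). Further down were the opioid peptide precursor PDYN (SD 0.83) and GPNMB (SD 0.93), a marker of phagocytic myeloid cells with group means of 5.43, 5.89 and 6.31 in control, medium and high dose (unadjusted p = 0.0519). The 4 measured genes of the dentate granule cell list averaged 7.92 in control, 8.15 at the medium and 7.93 at the high dose, so the medium dose stood apart. Its list mean differed from control by 0.21 (permutation p = 0.0266, adjusted p = 0.415). From medium to high dose the list mean shifted by -0.20 (permutation p = 0.00034, adjusted p = 0.0112). Between these doses camera did not call the list (adjusted p = 0.118, or 0.666 with an estimated correlation), nor did fry (adjusted p = 0.549), and no member passed. NEUROD1 was at -0.34 (SE 0.22, p = 0.141) and RGS14 at -0.22 (SE 0.18, p = 0.244). RGS14 was also in the list of CA pyramidal cell markers, so the list mean is not specific to dentate granule cells.

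The interferon difference among set codes was weighed first. An uneven spread of the feeding groups was excluded, since the set codes still differed with labels permuted within groups (permutation p = 0.00042, 52.8% of the variance). A batch marked by the spike-in, if its absence marks a batch at all, was excluded too, with permutation p = 0.024 in the 26 arrays that had it. A larger share of microglia that moves both list means equally was excluded, since interferon minus microglia means differed among set codes (permutation p = 0.0033). A share that moves the interferon mean more steeply was not excluded by this difference. Microglia means too were highest in S4 and S5 (7.46 and 7.52, against 7.25 to 7.39 in the others). A candidate explanation is a different immune exposure of some samples of S4 and S5. Not all of them were raised, since the interferon means ran from 7.23 to 7.51 in medium-dose S4 samples and from 7.2 to 8.77 in S5 controls. The labels do not say what the codes stand for, and no biological explanation was tested.

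For the lower interferon level at the medium dose, uneven set codes were excluded as the whole cause, with a shift of -0.436 (SE 0.167) with the set block and -0.44 (SE 0.222) with no block. A batch by the spike-in with the same effect in each set code was likewise excluded, with -0.437 (SE 0.166) when it was a second block. In the arrays that had the spike-in, the shift was -0.391 (SE 0.232), too imprecise to decide. A batch effect that differs between set codes was therefore not excluded. Samples of a single set code could account for much of the lower interferon level, since without S4 the shift was -0.195 (SE 0.152). S2 and S3 nevertheless lay on the same side with -0.229 and -0.312. Chance could not be excluded: in 19 of 100 splits within set codes, the most extreme of the 33 list means lay as far from 0 as this one (t of 2.61, highest other 3.56). An effect of the diet remains open.

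For the lower microglia level at the high dose, the measured interferon mean accounted for little, since the shift was -0.128 (SE 0.061) with that mean as covariate. The list mean may capture the interferon response of the tissue only in part, so this fit does not exclude that response. A single extreme control contributed, since the shift was -0.143 (SE 0.063) over all samples and -0.092 (SE 0.049) without control replicate 9. Whether that control was the whole cause cannot be told, since -0.092 lies between the values that would decide it. Chance could not be excluded: in 57 of 100 splits, the most extreme of the 33 list means, whichever list it was, lay as far from 0 as this one (t of 2.28, highest other 4.36).

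A real count of 0 is reached by every split, 100 of 100, so regrouping decides nothing about the passing probe sets. The highest others were 1, 7 and 3 for medium dose against control, high dose against control and the doses, 2 for any difference and 10 for the trend. Chance could not be excluded for the other counts. At unadjusted p under 0.05, 14 splits reached the real 1248 (highest other 2656), 47 reached 889 (highest other 3487) and 23 reached 1076 (highest other 2762). For lists called, 45 splits reached 6 (highest other 13), 80 reached 4 (highest other 13) and 47 reached 5 (highest other 11). The highest splits lay well above each of these real counts. Such an excess could reflect a structure of the samples beyond group and set code, but this was not tested.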
